A study of Homo sapiens with 8 samples.

How the data were processed

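Native RNA from 3 human cell lines was sequenced by direct RNA sequencing on Oxford Nanopore instruments, with total RNA as starting material per the labels. Reads were aligned with minimap2 to hg38, per the submitters' processing notes, and per the labels the deposited tables are TALON abundance tables, whose version is not given in the sources used here. Each of the 3 deposited tables holds read counts for 506946 transcript models, not normalized, per the file headers, of which 268821 had reads. Models are classed as known, incomplete splice match, new combination of annotated splice sites, unannotated splice site, genomic, antisense or intergenic. The length and exon number of each model are other values of the deposited tables. All 35496 known models and all 20565 annotated genes matched GENCODE release 29 by identifier, which gave coordinates on GRCh38. The shortest known model was 300 bases, and RNAs below that length were not analysed here.

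Read totals were 70374 to 461497 per library. A line with 0 reads was set at a floor of 3 counts over the line, 7.63 CPM for GM12878, 3.76 for HepG2 and 6.76 for K562. Floors and 95% counting intervals cover counting error only. Chi-square per degree of freedom between libraries of the same line was 1.35 to 4.65 over the 7 pairs, so none was counted as a repeat of another. The highest, 4.65, was that of the K562 pair, against 1.35 to 1.62 in GM12878 and 1.53 to 2.73 in HepG2.

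Counts of all models were summed by annotated gene. Genes were filtered with filterByExpr, normalised by TMM and tested with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest, R 4.3.3) in 1 fit over 8 libraries, two-sided, with Benjamini-Hochberg adjustment in each comparison. A gene was called at an adjusted p under 0.05, from a test against no change, and a fitted absolute log2 change of at least 1. CPM were computed over tested genes with TMM factors. Transcript usage was tested with diffSpliceDGE on known transcripts with at least 10 reads, in genes with at least 10 reads in each line, and called at an adjusted Simes p under 0.05 and a shift of at least 10 percentage points. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. After the results were seen, list tests were repeated over every split of the libraries of each comparison.

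The 26 lists fixed before the data were examined covered B cell identity, immunoglobulin constant regions and J chain, MHC class I and class II, NF-kB targets, hepatocyte secreted proteins, complement and coagulation, hepatocyte transcription factors, epithelial keratins and junctions, cholesterol synthesis, globins, erythroid identity, heme synthesis, cancer-testis antigens, interferon-stimulated genes, metallothioneins, glycolysis, mitochondrially encoded mRNAs, proliferation, ribosomal proteins, polyadenylated long noncoding RNAs, leukocyte and actin cytoskeleton, and markers of megakaryocytes and platelets, myeloid cells, T and NK cells, and fibroblasts and matrix. The last 4 and metallothioneins had too few tested genes for camera. Counts of list members cover those that passed the filter, and a member can pass through the line where it is high. A count of all tested members is therefore partly set in advance, and so are the direction and p of list tests over the same members. Fixed sizes were 22 for B cell identity, 14 each for immunoglobulins and MHC class II, 10 for globins, 20 for erythroid identity and 16 for cancer-testis antigens. Named genes followed a rule fixed before the data were examined: per direction, up to 10 called genes with the largest change after adding 10 CPM, at least 50 CPM in the higher line and no overlap of libraries; per list, the most abundant members and the called members of largest change; and for usage, up to 6 called genes of largest shift with at least 30 reads in each line. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen.

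Class shares and genes detected after hypergeometric thinning to 69635 reads were compared over all 560 assignments of libraries to lines, an exact permutation test whose smallest p is 0.00357. Class shares were also recomputed over 466 genes with at least 20 reads in every library, with the same weight for each gene in every library. Known-transcript length per gene was the read-weighted mean over genes with at least 10 known reads.

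Procedures were tested on simulated data. For genes, these simulations counted an adjusted p under 0.05 alone, in the right direction for recovery, without the fold threshold of the calls. In HepG2 against GM12878, of 100 genes changed 2-fold 32% were recovered and of 100 changed 4-fold 77%, over 4051 genes. Of the genes that passed, 6.03% were false. In K562 against GM12878 the same were 17%, 81% and 4.85% over 4024 genes, and in K562 against HepG2 32%, 80% and 6.67% over 4043 genes. Of 100 transcript shifts of 40 points, 35%, 34% and 32% were recovered in the 3 comparisons, and of 100 shifts of 20 points 14%, 13% and 11%. The permutation test gave a p under 0.05 in 7 of 100 draws without a difference. Camera at the preset correlation gave a p under 0.05 for 0, 0 and 2 of 100 unchanged lists in the 3 comparisons, with genes drawn independently of each other. Alternatives were another normalization, DESeq2 1.42.0, no filter, other read sets, a replicate block, other usage and list tests, and leaving out each library. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plotted with matplotlib 3.10.9.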

Results

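Direct RNA sequencing reads native RNA molecules through a nanopore without copying them into cDNA. It was applied to 3 established human lines: GM12878, a B-lymphoblastoid line, with 3 libraries, HepG2, a liver cancer line, with 3, and K562, a myelogenous leukaemia line, with 2. The stated purpose was to set such reads beside PacBio reads using TALON, a program that assigns each long read to a transcript model. The PacBio reads were not analysed here. Read totals ranged from 70374 in GM12878 replicate 3 to 461497 in HepG2 replicate 1, and averaged 132737 ± 55369 in GM12878 (SD, n = 3), 352061 ± 106625 in HepG2 (n = 3) and 228146 ± 120644 in K562 (n = 2). Of 20565 annotated genes, 17404 had a read and 4778 were abundant enough to test. Across genes, Pearson correlations of log2(CPM + 1) were 0.597 to 0.854 for the 7 pairs of libraries of the same line and 0.307 to 0.522 for the 21 pairs of different lines, and genes are not independent replicates. Labels do not say whether libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The spread of a gene was estimated over all 8 libraries, so K562 calls assume that K562 varies like the other lines. By chi-square the K562 libraries differed more from each other than those of the other lines did. Values in CPM, read counts scaled to library size, are means over libraries ± SD, and intervals and floors cover counting error only.

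**Figure D1:**
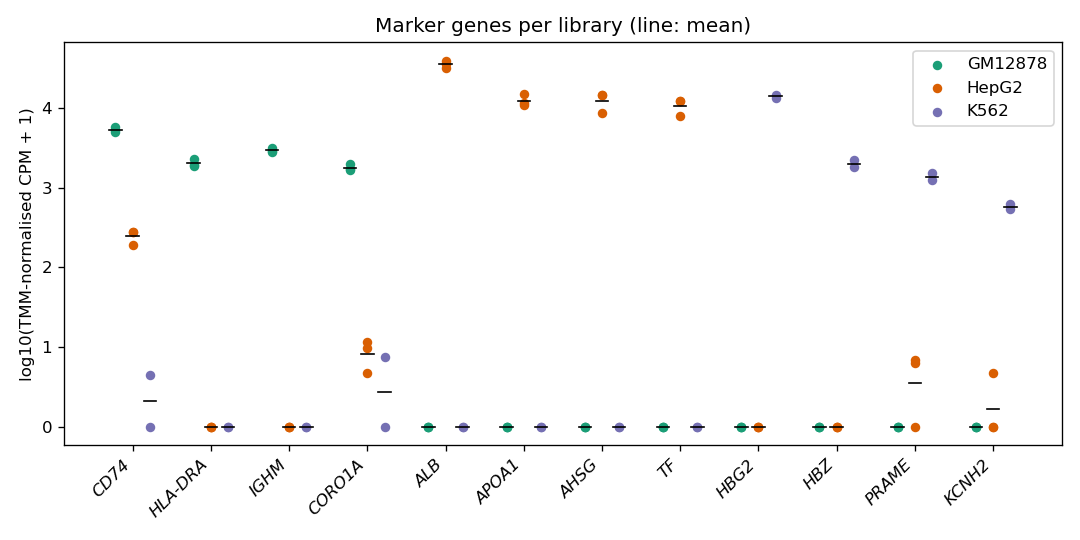
Each point is 1 library and each short bar the mean of a line's points, on a log10 scale of TMM-normalised CPM with 1 added. CD74, HLA-DRA, IGHM and CORO1A lay highest in GM12878, ALB, APOA1, AHSG and TF in HepG2, and HBG2, HBZ, PRAME and KCNH2 in K562.

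Genes of secreted liver proteins were far higher in HepG2, and genes of antigen presentation and B cells far higher in GM12878. ALB, the serum albumin gene (ENSG00000163631.16, chromosome 4, 73397114 to 73421412, GRCh38), was at 35400 ± 3790 CPM in HepG2 (n = 3) and had 0 reads in GM12878 (n = 3), at least 4640-fold higher. AFP, the fetal albumin relative alpha-fetoprotein, was at 18300 ± 1870 CPM, at least 2400-fold higher, and SERPINA1, a protease inhibitor, was at 29100 ± 2110 CPM against 7.76 ± 13.4, from 4 reads in GM12878 replicate 2. In the other direction IGHM, the immunoglobulin mu constant region, was at 2940 ± 169 CPM in GM12878 and 0 reads in HepG2, at least 783-fold higher in GM12878. TMSB4X, an actin-binding thymosin, was at 14300 ± 584 CPM in GM12878 and 11.8 ± 13.4 in HepG2.

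Among the genes of largest change, AHSG, APOA1, A2M, TF, APOA2, AKR1C1 and APOH also had 0 reads in GM12878, with HepG2 levels from 12500 ± 3400 CPM for AHSG to 5740 ± 79.7 for APOH. AKR1C1 shares sequence with close paralogs and its value of 8470 ± 271 CPM is uncertain. HLA-DRA, HLA-DRB1, IGLC2, CCL3 and HLA-DPA1 had 0 reads in HepG2. The detoxification gene GSTP1, at 1420 ± 114 CPM in GM12878, and LDHB, a lactate dehydrogenase subunit at 1200 ± 189 CPM, also had 0 HepG2 reads, at least 378-fold and 320-fold lower. CORO1A, a leukocyte actin regulator, was at 1780 ± 165 CPM against 7.71 ± 3.59. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2348 of 4778 genes were called with a fitted change of at least 2-fold, 1338 higher in HepG2 and 1010 higher in GM12878. The adjusted p of that test was 5.07e-36 for ALB and 1.25e-29 for IGHM. It tests against no change, so a true change of 2-fold is not shown for each call. HBQ1, for instance, was called with a bound of 1.76-fold.

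All 23 tested genes of hepatocyte secreted proteins were higher in HepG2, as were all 15 of complement and coagulation and all 6 hepatocyte transcription factors. These lists were fixed with 26, 23 and 14 members, and members that did not pass the filter are not counted. The median log2 change, with genes at 0 reads set to their bound, was 8.41, 6.06 and 3.97 in turn. The same 23, 15 and 6 were called when adjusted over the list alone. C3, the central complement protein, was at 2940 ± 464 CPM, FGG, a fibrinogen chain, at 1300 ± 186, and the liver regulators CEBPA and HNF4A at 393 ± 79.1 and 159 ± 31.9. Camera's adjusted p was 1.54e-17, 1.75e-10 and 0.000123 for these lists, and all 3 held with an estimated correlation. Camera tested the same filtered members, so its direction and p are partly set in advance as well. Camera at its preset correlation also called 8 to 13 lists in each of the 9 other splits of these libraries, where no gene was called. With an estimated correlation, 9 lists were called in the real split and 0 in the others. Each other split put libraries of both lines on both sides, which keeps part of the line difference and adds the rest to the spread. Such splits are no reference without a difference, so neither count tests the list calls. Of 19 cholesterol synthesis genes 17 were higher in HepG2 and 2 lower, also when adjusted over the list alone. INSIG1, a brake on the pathway, had 0 reads in HepG2 and 38.7 ± 4.74 CPM in GM12878. Camera's adjusted p for cholesterol synthesis was 0.000684, and the adjusted p = 0.266 with an estimated correlation. Epithelial keratins and junctions had 4 of 6 genes higher, over all genes and adjusted over the list alone, led by KRT8 at 1580 ± 80.9 CPM. That list had a camera adjusted p of 0.00637 and an adjusted p = 0.275 with an estimated correlation.

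All 18 tested B cell identity genes were higher in GM12878, over all genes and adjusted over the list alone. CD79A, part of the B cell receptor, was at 404 ± 28.8 CPM, and MS4A1, which encodes CD20, at 342 ± 129. The camera adjusted p of the B cell list was 6.31e-12, and the adjusted p = 0.072 with an estimated correlation. Here too, and for the lists below, camera covers only members that passed the filter. All 9 tested MHC class II genes, all 5 of immunoglobulin constant regions and J chain, 14 of 15 of the leukocyte and actin cytoskeleton, 13 of 16 NF-kB targets and 14 of 22 proliferation genes were higher in GM12878, with the same counts adjusted over the list alone and none higher in HepG2. CD74, the class II chaperone, was at 5350 ± 439 CPM in GM12878 and 248 ± 51.9 in HepG2. MKI67, a marker of cycling cells, was at 123 ± 45.8 against 10.3 ± 11.1 CPM. Camera's adjusted p for these 5 lists was 4.4e-09, 3.24e-05, 1.59e-10, 2.92e-07 and 3.24e-05, and each held with an estimated correlation.

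MHC class I genes were higher in GM12878 in 9 of 11 cases, over all genes and adjusted over the list alone, with HLA-B at 2450 ± 30.9 against 61 ± 29.7 CPM. HLA genes are polymorphic and related in sequence, and their separate values are uncertain. Camera's adjusted p for MHC class I was 4.97e-05, and the adjusted p = 0.072 with an estimated correlation. Interferon-stimulated genes were higher in GM12878 in 11 of 14 cases and higher in HepG2 in 1, IFITM3, at 242 ± 32.1 CPM against 0 reads. The camera adjusted p of that list was 0.000974 and held with an estimated correlation. Ribosomal proteins did not pass (1 of 78 higher, RPS27, and 1 lower, RPL35), and their median log2 change of 0.06 and mean of 0.05 were of the other sign than camera's direction. Glycolysis (2 higher, 4 lower of 16), mitochondrially encoded mRNAs (1 of 9 higher), heme synthesis (1 higher and 1 lower of 7) and polyadenylated long noncoding RNAs (3 higher and 3 lower of 12) did not pass camera, with the same counts adjusted over the list alone. By fry, heme synthesis (adjusted p 0.000231) and glycolysis (0.00266) passed, and ribosomal proteins, mitochondrially encoded mRNAs and long noncoding RNAs did not. Cholesterol synthesis (fry adjusted p 0.000296), epithelial genes (3e-06), B cell identity (2.54e-06) and MHC class I (2.25e-05) also passed fry. Erythroid identity did not pass, with 2 higher and 1 lower of 17, a median log2 change of 0, a mean of -0.44, camera's direction down and fry's up. Of 7 globins HBQ1 was higher, at 13.4 ± 7.02 CPM, and 0 were when adjusted over the list alone, and of 8 cancer-testis antigens none was called by edgeR; neither list passed camera. Metallothioneins had 1 higher and 1 lower of 3. Some markers of other cell types were read in 1 of the lines only: LYZ, the lysozyme gene, at 1780 ± 210 CPM and CD7, a lymphocyte surface protein, at 744 ± 114 CPM in HepG2 with 0 reads in GM12878. TRAC, a T cell receptor constant region, was at 254 ± 38.6 CPM and PLEK, a platelet substrate, at 352 ± 74 CPM in GM12878 with 0 reads in HepG2. FN1, fibronectin, was at 926 ± 62.8 CPM in HepG2 with 0 reads in GM12878, and VIM, vimentin, at 412 ± 57.4 in GM12878 with 0 reads in HepG2.

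K562 RNA carried embryonic and fetal globins and cancer-testis antigens, and had less antigen presentation RNA than GM12878. HBG2, a fetal gamma-globin gene, was at 14000 ± 862 CPM in K562 (n = 2) with 0 reads in GM12878 (n = 3), at least 1840-fold higher. HBE1 and HBZ, the embryonic globins, were at 5110 ± 92 and 2000 ± 284 CPM, and PRAME, a tumour antigen, at 1370 ± 197. HLA-B was at 2450 ± 30.9 CPM in GM12878 with 0 reads in K562, at least 363-fold lower. CD74 had 1 read in K562, a ratio of 2420 with a 95% counting interval of 434 to 95700.

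HBG1, HBA1, HBA2, AC104389.5, GAGE12F and KCNH2, a potassium channel gene, were the other genes of largest increase, and IGHM, IGLC2, HLA-DRA, HLA-DRB1, CORO1A, CCL3 and HLA-DPA1 were among those of largest decrease. HBG1 with HBG2, HBA1 with HBA2 and the GAGE family are near-identical copies, and their separate values are uncertain, as are those of the HLA genes. AC104389.5, at 1750 ± 38.3 CPM in K562, overlaps both gamma-globin genes on chromosome 11 and is uncertain as well. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1371 of 4778 genes changed, 662 higher in K562 and 709 higher in GM12878, with an adjusted p of 1.63e-31 for HBG2 and 3.94e-24 for HLA-B. Camera called 13 lists, 9 with an estimated correlation, against 1 to 12 and 0 in the 9 other splits of these libraries. Those splits mixed the lines and are no reference without a difference. DESeq2's Wald test called 896. Without K562 replicate 2, the deeper of the pair, 392 of these calls were lost, and the log2 changes of PCK2, BTBD2, C16orf58, PINK1 and SLC6A9 changed sign without passing the test; they are named after their values were seen.

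All 7 tested globins, 16 of 17 erythroid identity genes and all 8 cancer-testis antigens were higher in K562, also when adjusted over the list alone. GATA1, the erythroid master regulator, was at 312 ± 65.6 CPM with 0 reads in GM12878, and BLVRB, an erythrocyte reductase, at 1200 ± 449 against 17.7 ± 9.07. TFRC, the transferrin receptor, was the erythroid gene that did not pass, at 184 ± 51.1 against 106 ± 40.7. Camera's adjusted p was 1.2e-11, 1.28e-13 and 1.96e-10, and all 3 held with an estimated correlation. Camera tested only members that passed the filter, so its direction and p are partly set in advance. HBG2, HBG1, HBE1, GAGE1 and SSX1, for instance, had 0 reads in both GM12878 and HepG2. Heme synthesis had 4 of 7 genes higher and 1 lower, ALAS1, with UROD at 782 ± 86.6 against 82.2 ± 5.82 CPM, with the same counts adjusted over the list alone. Its camera adjusted p was 0.0294, and the adjusted p = 0.113 with an estimated correlation. Epithelial keratins and junctions had 4 of 6 higher, also when adjusted over the list alone, with KRT18 at 569 ± 34.2 CPM and 0 reads in GM12878, at a camera adjusted p of 0.000679 and an adjusted p = 0.182 with an estimated correlation.

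All 18 B cell identity genes, all 9 of MHC class II, all 11 of MHC class I, all 5 immunoglobulin genes and all 16 NF-kB targets were higher in GM12878, with the same counts adjusted over the list alone. B2M, the class I light chain, was at 2010 ± 11.2 against 235 ± 38.6 CPM, and NFKBIA, the inhibitor of NF-kB, at 272 ± 18.9 against 11.9 ± 7.61. The camera adjusted p was 1.21e-14, 1.29e-12, 2.42e-10, 7.58e-07 and 1.29e-12. For B cell identity the adjusted p = 0.0518 with an estimated correlation, and the other 4 lists held. The leukocyte and actin cytoskeleton list had 13 of 15 higher in GM12878, also when adjusted over the list alone, at a camera adjusted p of 1.28e-09, and held with an estimated correlation. Interferon-stimulated genes had 10 of 14 higher in GM12878 and 2 higher in K562, IFITM1 and IFITM3, with 11 and 2 when adjusted over the list alone. The camera adjusted p of that list was 9.98e-05 and held with an estimated correlation. Mitochondrially encoded mRNAs had 4 of 9 higher in GM12878, 5 adjusted over the list alone, at a camera adjusted p of 0.00761 and an adjusted p = 0.4 with an estimated correlation. Mitochondrial reads were 0.838% ± 0.176 of a GM12878 library and 0.297% ± 0.16 of a K562 library. By fry, B cell identity (adjusted p 4.61e-06) and mitochondrially encoded mRNAs (0.0306) passed, as did heme synthesis (3.13e-07) and epithelial genes (1.39e-05).

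Glycolysis did not pass, with 3 of 16 higher and 2 lower, a median log2 change of -0.33, a mean of 0.30 and camera's direction down. PKM, the pyruvate kinase gene, was at 474 ± 110 CPM in K562 against 2040 ± 290, and the hexokinase gene HK1 at 545 ± 166 against 65.7 ± 20.7. Cholesterol synthesis (4 higher and 1 lower of 19), proliferation (5 of 22 lower), ribosomal proteins (4 of 78 higher) and long noncoding RNAs (5 higher and 1 lower of 12, 6 and 1 adjusted over the list alone) did not pass camera. Of these lists and glycolysis, only proliferation passed fry, at an adjusted p of 0.0134. Hepatocyte secreted proteins, complement and coagulation and hepatocyte transcription factors passed neither camera nor fry. Their calls were APOC1 and APOE higher, and SERPINA1 and F5 lower in K562, and the lower ones were 0 when adjusted over the list alone. The SERPINA1 call rested on 4 reads in GM12878 replicate 2, and without that library its log2 change was 0. FN1 was higher in K562, at 13.4 ± 0.581 CPM with 0 reads in GM12878, among 3 fibroblast and matrix genes, 2 of them adjusted over the list alone. PLEK and TRAC had 0 reads in K562, and LYZ and CD7 were near the floor in both lines. The 3 metallothioneins tested were lower in K562, with MT1E at 322 ± 27.9 CPM in GM12878 and 0 reads in K562.

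K562 RNA was richer in globins and HepG2 RNA in genes of secreted liver proteins. HBG2 was at least 3730-fold higher in K562, at 14000 ± 862 CPM (n = 2) with 0 reads in HepG2 (n = 3), and ALB at least 5240-fold lower. IFITM1, an interferon-induced membrane protein, was at 1140 ± 37.5 CPM in K562 with 1 read in HepG2, a ratio of 913 with a 95% counting interval of 163 to 36100. GSTP1 and LDHB, at 1900 ± 333 and 857 ± 56.1 CPM in K562, had 0 reads in HepG2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2105 of 4778 genes changed, 830 higher in K562 and 1275 higher in HepG2, with an adjusted p of 1.64e-33 for HBG2 and 1.68e-33 for ALB. Camera called 11 lists, 7 with an estimated correlation, against 1 to 12 and 0 in the 9 other splits of these libraries. Those splits also mixed the lines and are no reference without a difference. Without K562 replicate 2, 357 of these calls were lost, and the log2 changes of AARS, DNASE2, MTPN, EMID1 and KIFC1 changed sign without passing the test, as did ERVK3-1 without K562 replicate 1 and PCBD1 with known transcripts only; these are named after their values were seen.

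AMBP, which encodes a plasma protease inhibitor, was at 6430 ± 603 CPM in HepG2 with 0 reads in K562, and SERPINA1, AFP, AHSG, APOA1, A2M, TF, APOA2 and APOH also had 0 K562 reads. All 23 hepatocyte secreted proteins, 15 of 15 complement and coagulation genes and 6 of 6 hepatocyte transcription factors were higher in HepG2, also when adjusted over the list alone. All 7 globins, 17 of 17 erythroid identity genes and 8 of 8 cancer-testis antigens were higher in K562, also when adjusted over the list alone. Camera's adjusted p was 1.96e-19, 8.65e-12 and 9.09e-05 for the liver lists and 1.37e-09, 3.54e-12 and 4.41e-09 for the K562 lists, and all 6 held with an estimated correlation. These lists too were tested only over members that passed the filter. Proliferation genes were higher in K562 in 10 of 22 cases and lower in 1, UBE2C, at a camera adjusted p of 0.000738 that held. The counts were the same adjusted over the list alone. MCM7, a replicative helicase subunit, was at 750 ± 31.3 against 153 ± 33.7 CPM.

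The leukocyte and actin cytoskeleton list had 7 of 15 genes higher in K562, 8 adjusted over the list alone, at a camera adjusted p of 0.0189 and an adjusted p = 0.105 with an estimated correlation. TMSB4X was at 991 ± 154 CPM in K562 against 11.8 ± 13.4. Cholesterol synthesis had 14 of 19 higher in HepG2 and INSIG1 higher in K562, with 15 and 1 adjusted over the list alone, at a camera adjusted p of 0.00408 and an adjusted p = 0.372 with an estimated correlation. MHC class I had 7 of 11 higher in HepG2, also when adjusted over the list alone, at a camera adjusted p of 0.00521 and an adjusted p = 0.211 with an estimated correlation. Mitochondrially encoded mRNAs had 6 of 9 higher in HepG2, also when adjusted over the list alone, at a camera adjusted p of 0.00819 and an adjusted p = 0.392 with an estimated correlation. Ribosomal proteins (1 higher and 1 lower of 78), interferon-stimulated genes (2 and 7 of 14), heme synthesis (4 and 1 of 7), glycolysis (4 and 1 of 16), B cell identity (2 and 0 of 18), immunoglobulin genes (0 of 5), MHC class II (1 lower of 9) and epithelial genes (1 lower of 6) did not pass camera, with the same counts adjusted over the list alone. NF-kB targets had 2 higher and 4 lower of 16, 1 and 4 adjusted over the list alone, and long noncoding RNAs 4 and 2 of 12, 5 and 2 adjusted over the list alone, and neither passed camera. By fry all lists of this paragraph tested so far passed except ribosomal proteins, interferon-stimulated genes, B cell identity and immunoglobulin genes. Fry's adjusted p was 1.2e-06 for heme synthesis, 0.00857 for glycolysis, 0.00293 for NF-kB targets and 0.011 for long noncoding RNAs. LYZ and CD7 were higher in HepG2, and 2 of 3 metallothioneins were. VIM, the vimentin gene, was at 632 ± 453 CPM in K562 with 0 reads in HepG2, and FN1, fibronectin, at 926 ± 62.8 CPM in HepG2 against 13.4 ± 0.581. The 3 fibroblast and matrix genes tested had a median log2 change of -2.33 and a mean of 0.56, and were too few for camera.

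Of 676 genes tested for the annotated transcripts they used, 11 differed between HepG2 and GM12878, 4 between K562 and GM12878 and 6 between K562 and HepG2 by edgeR's diffSpliceDGE with Simes and Benjamini-Hochberg adjustment, and 29, 6 and 19 by its F test. Of simulated shifts of 40 percentage points 35%, 34% and 32% were recovered in the 3 comparisons, and of 20 points 14%, 13% and 11%, so genes not called are not shown to be unchanged. Usage percentages are of a gene's reads on its tested known transcripts, not of all its reads. NDUFS5, a complex I subunit on chromosome 1, had 91.5% ± 1.38 of these reads on NDUFS5-201 in GM12878 (n = 3), 49% ± 11.4 in HepG2 (n = 3) and 38.9% ± 8.64 in K562 (n = 2). NDUFS5-201 is annotated at 544 bases and the other NDUFS5 transcript tested at 548, each with 3 exons and the same ends. They share 1 intron, and each has 1 that the other lacks. Whether reads were assigned correctly between such similar transcripts was not tested. ETFB, an electron transfer flavoprotein gene on chromosome 19, had 76.6% ± 3.02 of its tested known-transcript reads on ETFB-202 in HepG2 and 16.2% ± 2.75 in K562. RPL14, a ribosomal protein gene on chromosome 3, had 99% ± 0.963 of such reads on a transcript of 794 bases and 5 exons in GM12878 and 73% ± 2.03 in K562. RPL14-201, annotated at 7072 bases and 6 exons, held 25.4% ± 1.66 in K562 and 10.7% ± 0.798 in HepG2. It shares 4 introns with the transcript of 794 bases and adds 1. Both lengths are those of the annotation, and read lengths were not examined, so RNA of 7072 bases is not shown.

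In HepG2 against GM12878 ACOT7, ACP1, SSNA1, ATP5MC1, APEX1, ETFB, ATP5F1B, HSPA8, P4HB and RPL14 were called beside NDUFS5; ETFB, ATP5F1B, HSPA8, P4HB and RPL14 are named there after their values were seen. ACOT7-210 fell from 100% to 53.5% ± 11.8, ACP1-201 from 95.4% ± 4.09 to 51.3% ± 14.5, and APEX1-210 from 37.8% ± 6.44 to 1.23% ± 2.14. ALDOA, the aldolase gene, used ALDOA-206 for 37.8% ± 8.4 of its tested known-transcript reads in GM12878 and 7.16% ± 0.589 in K562. PSMB10 was called in K562 against GM12878 on 28 K562 reads and was named after its values were seen. METTL26, NUDC, CENPX, ACOT7, ETFB and RPL14 were called in K562 against HepG2, NUDC-201 at 96% ± 5.66 in K562 and 51.4% ± 8.05 in HepG2; CENPX and ACOT7 are named there after their values were seen. None of 9 tested genes of the fixed splicing list was called in any of the 3 comparisons by diffSpliceDGE's Simes or F test, and 2, 2 and 0 of them had an unadjusted p under 0.05, against 88, 44 and 74 of all genes. For HepG2 against GM12878 the count was 5 without GM12878 replicate 2, 6 without GM12878 replicate 1, HepG2 replicate 1 or HepG2 replicate 2, 7 without GM12878 replicate 3 or HepG2 replicate 3, and 17 without either K562 library. For K562 against HepG2 it was 1 without HepG2 replicate 3, 2 without HepG2 replicate 2 and 3 without K562 replicate 2.

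Of 10 transcript model classes and groups of classes, 3 differed between the lines after adjustment: known transcripts, models with unannotated splice sites, and the latter joined with new combinations of annotated ones. Reads on known transcripts were 44.8% ± 0.736 of a GM12878 library (n = 3), 39.2% ± 1.91 of a HepG2 library (n = 3) and 47.4% ± 0.0927 of a K562 library (n = 2), by an exact permutation test p = 0.00357, the smallest it can give, and adjusted p = 0.0357. Over annotated genes the difference of HepG2 from the mean of the other lines was -6.99 points. Over the 466 genes with at least 20 reads in every library it was -2.65 points with each library's own weights (exact permutation p = 0.1) and -3.81 points with equal gene weights (exact permutation p = 0.0893), where HepG2 libraries were not all on one side, so the difference did not pass within these genes. Over the 393 of them that are not ribosomal protein genes, a set chosen after the results were seen, it was -5.20 points with equal weights, exact permutation p = 0.0429, not adjusted. Incomplete splice matches, models that hold part of a known transcript's introns, were 26.2% ± 1.26 in HepG2 against 18.1% ± 0.227 in GM12878 and 18.1% ± 0.571 in K562, exact permutation p = 0.0357, adjusted p = 0.0595, which did not pass. Those missing the 5' end were 21.7% ± 1.04, 14.5% ± 0.214 and 14.5% ± 0.56, with the same exact permutation p and adjusted p. Incomplete splice matches took 24.8% to 27% of reads in HepG2 libraries and 17.7% to 18.5% in the others, without overlap. The test compares all 3 lines at once, and regrouping libraries of 2 lines with like values hardly changes its statistic. With GM12878 and K562 alike, its p stays well above the smallest value however large the HepG2 excess. Not passing therefore does not argue against that excess. Models with splice sites that are all annotated in other combinations, and models with unannotated splice sites, together held 25.8% ± 1.15, 22.4% ± 0.632 and 24.2% ± 0.561 in GM12878, HepG2 and K562, exact permutation p = 0.0143, adjusted p = 0.0476. The latter alone were 8.55% ± 1.09, 5.38% ± 0.485 and 6.47% ± 0.485, exact permutation p = 0.00714, adjusted p = 0.0357. The antisense class, 0.471% ± 0.0227, 0.191% ± 0.00327 and 0.196% ± 0.0173, had an exact permutation p = 0.0286 and an adjusted p = 0.0595, and genomic models, 10.8% ± 1.27, 11.8% ± 0.418 and 9.98% ± 0.107, an exact permutation p = 0.207.

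**Figure D2:**
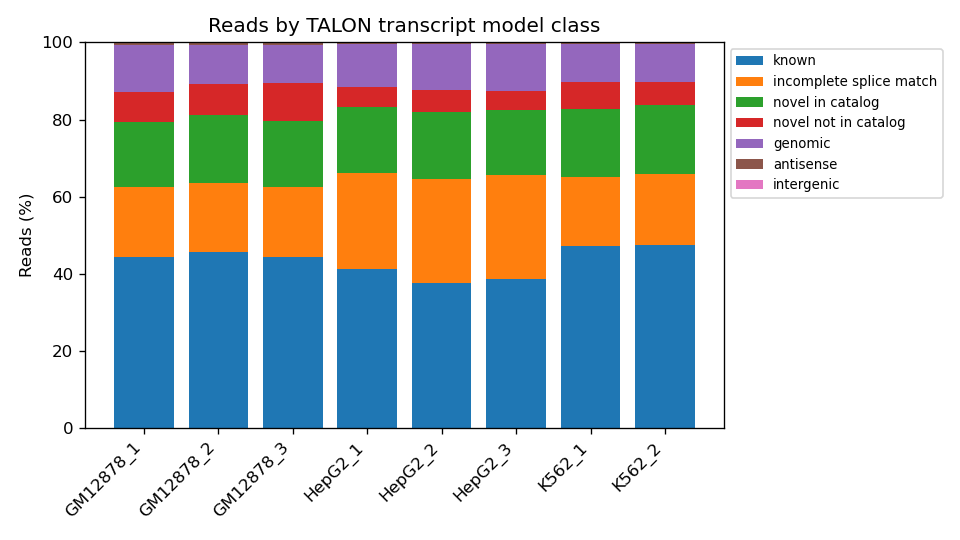
Bars stack the percentage of each library's reads by transcript model class. Incomplete splice matches took 24.8% to 27.0% of the reads in HepG2 libraries.

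Of 6 abundant genes examined in every line, 4 showed the HepG2 pattern, among them EEF1A1, the elongation factor gene, and RPLP0, a ribosomal protein gene; the genes of this paragraph were chosen after their values were seen. Incomplete splice matches held 33.8% ± 6.3 of EEF1A1 reads in HepG2 against 21.3% ± 1.12 in GM12878 and 22.7% ± 0.321 in K562, and 24.6% ± 3.38 of RPLP0 reads in HepG2 against 15.2% ± 0.777 and 11.2% ± 2.14. HepG2 was also highest for ACTB, an actin gene, at 40.3% ± 2.92 against 30.7% ± 2.8 and 33.4% ± 0.974, and for the glycolysis gene GAPDH, at 27.9% ± 3.13 against 19.5% ± 1.83 and 24.2% ± 0.85. For FTL, a ferritin chain, they were 3.15% ± 0.869 in HepG2, 2.28% ± 1.49 in GM12878 and 1.76% ± 0.464 in K562, and for RPS2 1.83% ± 0.983, 1.41% ± 0.324 and 0.914% ± 0.382, where HepG2 and GM12878 differed by less than the larger of their SDs. In HepG2 they held 68.6% ± 4.12 of SERPINA1 reads and 79.4% ± 1.82 of A2M reads, and 0.0646% ± 0.0172 of APOA1 reads. Ribosomal protein genes held 33.2% of the reads on new combinations of annotated splice sites (mean of 8 libraries): RPS2 had 76.5% of its 11680 reads on 1 such model, and RPS15A 85.8% of 6144. Of 54981 models with unannotated splice sites, 85.3% had 1 read in all 8 libraries together.

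**Figure D3:**
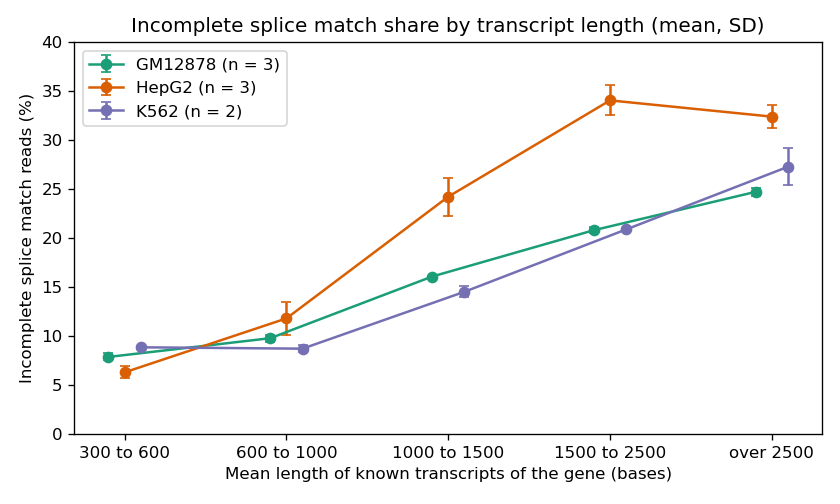
Points are line means and bars SDs of the percentage of reads on incomplete splice matches, against the read-weighted mean length of each gene's known transcripts in bases. HepG2 lay at 6.30% against 7.88% in GM12878 and 8.86% in K562 from 300 to 600 bases, at 34.1% against 20.8% and 20.9% from 1500 to 2500 bases, and at 32.4% against 24.7% and 27.3% over 2500 bases. Lengths are those of annotated models and not of reads, and place A2M at 1113 bases and TF at 20313. Gene weights are each library's own, so ALB, SERPINA1, AFP and AHSG enter the HepG2 value from 1500 to 2500 bases. With equal weights over genes read in every library that bin held 22.9% against 17.2% and 17.3%, and 300 to 600 bases 8.08% against 7.10% and 7.09%.

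At an equal depth of 69635 reads no difference between the lines was detected in the number of annotated genes with a read, 7955 ± 211 in GM12878, 7763 ± 152 in HepG2 and 7756 ± 286 in K562, exact permutation p = 0.475. Without thinning, HepG2 had the most, 11725 ± 787 against 9345 ± 1322 in GM12878 and 10470 ± 1756 in K562, exact permutation p = 0.164.

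**Figure D4:**
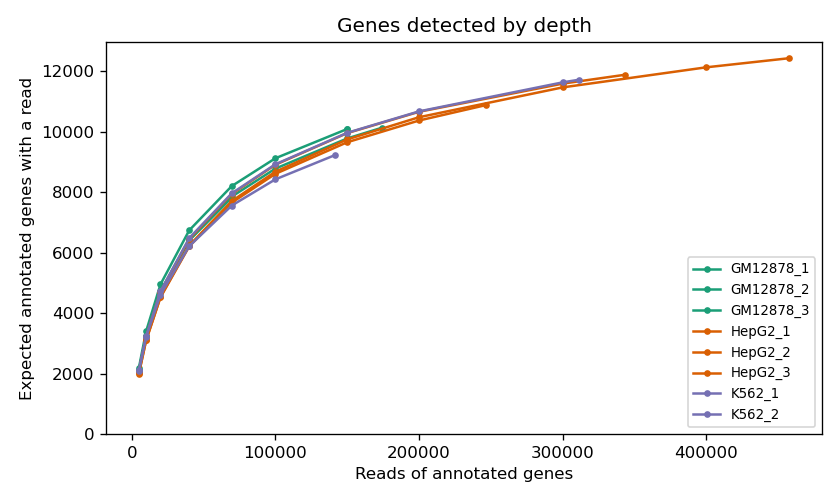
Curves give the expected number of annotated genes with a read against reads drawn, per library, coloured by line. At 69635 reads the libraries lay between 7554 and 8197 genes.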

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

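The tests of intron overlap in usage genes, of the AC104389.5 exons, of weights within shared genes, without ribosomal protein genes, by length bin, of the excess relative to the other lines and of other groupings were chosen after the results were seen.

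Genes absent from the annotation lay outside the gene tests, and some of those with most reads were read mainly in 1 line. They stood above the limit that a count of 0 allows, and how strand was used in counting is not given in the sources used here. The antisense gene ENCODEHG000048829 had 916 reads in GM12878, 5 in HepG2 and 62 in K562, and made up 49.3% of GM12878 reads in the antisense class. The intergenic genes ENCODEHG000065952 and ENCODEHG000049928 had 461 and 153 reads in HepG2 and 0 in the other lines, and ENCODEHG000050052 had 282 in HepG2, 0 in GM12878 and 3 in K562.

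HepG2 had 8.18 percentage points more reads on incomplete splice matches than the mean of the other lines over annotated genes. With equal gene weights over the 466 genes read in every library, the excess was 4.086 points (exact permutation p = 0.0571), and over the 393 of them that are not ribosomal protein genes it was 5.42 points (exact permutation p = 0.00714, HepG2 SD 1.46). A threshold of 4.089, set before the value was seen, would have counted this in favour of a different set of expressed genes; a margin of the largest SD, 1.56, was required only afterwards, and with it this explanation cannot be told apart from others, as both values lie within their spread of the threshold. Within the shared genes, different weights were argued against: the excess was 3.01 points with each library's own weights and 4.09 with equal weights. Stronger 5' truncation of HepG2 RNA or reads may contribute, as the excess was 4.06 points larger for genes with transcripts of 1500 bases or more than under 1000 bases, against a spread of 0.594. With equal gene weights it was 0.982, 2.31, 4.25, 5.69 and 6.93 points in 5 bins of rising length, but with each library's own weights it did not rise steadily: HepG2 lay below both other lines from 300 to 600 bases, and over 2500 bases at 32.4% against 24.7% and 27.3%. Long genes started higher, and relative to the other lines the excess was 31% ± 8.35 against 22% ± 15, a difference of 8.99 ± 7.33 (exact permutation p = 0.0857), so an excess in proportion to that start is not ruled out. Lengths here are those of the annotated known models to which reads were assigned, and not of reads or RNA. Truncated reads assigned to a shorter known model may change them, so the length groups do not measure RNA length. RNA handling, sequencing run and a biological difference between the lines were not separated by any test.

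Usage calls may in part count truncated reads as shorter annotated transcripts, which these values leave open. In 13 of the 21 called gene comparisons, 1 of the 2 most moved transcripts held only the 3' part of the other's introns, among them ATP5F1B, HSPA8, P4HB and NUDC. NDUFS5, ACP1, ACOT7, ALDOA, CENPX and METTL26 differed by other splicing. The transcript with the 3' part was the shorter in 8 of the 13 and the longer in 5, among them ETFB-202. These are lengths of annotated models and not of reads, so they do not argue for or against truncation. In HepG2 against GM12878 it gained in 6 genes and lost in 2, ATP5MC1 and RPL14. The need for it to be shorter was added after these counts were seen, and without it the 13 would have counted in favour; a biological change of transcript start was not tested.

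AC104389.5 reads in K562 could be reads shared with the near-identical gamma-globin genes. All of its annotated exon bases, 100%, lay in exons of HBG2 (the first 2 exons) or HBG1 (the last). Its reads were 6.19% and 6.87% of the reads of the 3 genes in K562 replicates 1 and 2, and a joined transcript of the locus stays open.

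For HepG2 against GM12878, only 10 splits of the 6 libraries exist, too few for a share under 0.05. The real split called 2348 genes and the highest other 0, with 1 split as large. For transcript usage it called 11 genes and the highest other 0, with 1 split as large. For gene lists by camera at its preset correlation it called 13 and the highest other 13, with 3 splits as large and 8 to 13 lists in every split. With an estimated correlation the count was 9 against 0 in every other split, a test added after the results were seen. Every other split put libraries of both lines on both sides, which keeps part of the line difference and adds the rest to the spread. Counts of 0 are therefore likely there, lists called there can come from the line difference, and none of these counts tests the calls.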

How the results depend on the processing

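The alternatives were all planned before the results were seen. Another normalization changed no count of called genes by over 1.5 times. With no filter, 3746 genes were called in HepG2 against GM12878 and 3298 in K562 against HepG2, as more genes were tested. With known transcripts only, 777, 459 and 714 genes were called in the 3 comparisons, as fewer were tested. DESeq2's Wald test called 896 genes in K562 against GM12878, and the cause was not tested. The gene-level F test of usage called 29 genes in HepG2 against GM12878 and 19 in K562 against HepG2, and the cause was not tested. Leaving out 1 library gave 5 to 17 usage calls in HepG2 against GM12878 and 1 to 6 in K562 against HepG2; with 1 K562 library left, it is assumed to vary like the other lines. Gene lists called in K562 against HepG2 numbered 7 for camera with an estimated correlation and 17 for fry, and the cause was not tested.

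The replicate block was fitted although replicate numbers do not pair the libraries: same-numbered libraries of different lines had deviation correlations of -0.0736 to 0.0475. It gave 2309, 1291 and 1998 called genes, and 10, 4 and 1 usage genes, against 11, 4 and 6 without it.

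For the percent of reads on incomplete splice match models by line, the HepG2 excess over the lowest line, 8.16 points, was 7.75 to 8.88 points with 1 library left out. With 1 HepG2 library left out the exact permutation p was 0.0952, against 0.0143 or 0.0286 with 1 library of another line left out. That p counts assignments of libraries to lines and so depends on the group sizes, which differ between these settings. The higher p therefore does not show a weaker excess. For annotated genes detected at equal depth by line, the difference of GM12878 and K562, 199 genes, was -1125 without thinning, where depth differs, and -3.32 to 401 with 1 library left out, the lowest without K562 replicate 1. None of these settings gave an exact permutation p under 0.05. The mean replicate correlation across genes, 0.734, was 0.892 with a pseudocount of 10 CPM, 0.94 over genes with at least 10 reads in both libraries, and 0.445 over known transcripts. A simulated 4-fold change was recovered in 77%, 81% and 80% of genes, and a 2-fold change in 32%, 17% and 32%, so an uncalled gene is not shown to be unchanged. Recovery was counted by adjusted p alone, without the fold threshold of the calls, which can only lower it.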

Other observations

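These summaries were chosen after the results were seen. Ribosomal protein genes took 21.6% ± 0.949 of GM12878 reads, 17.4% ± 0.68 of HepG2 reads and 24.4% ± 2.86 of K562 reads. Their reads lay on known transcripts in 52.5% to 59.9% of cases per library, and reads of other genes in 34.6% to 44.7%. Of the 60 most abundant genes, 48 were led by a known model, 9 by a new combination of annotated splice sites and 3, SERPINA1, A2M and TF, by an incomplete splice match.

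Leaving out the lead antisense gene, antisense reads were 0.238% ± 0.0152 of GM12878, 0.19% ± 0.00278 of HepG2 and 0.181% ± 0.0118 of K562 libraries.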
